A study of Mus musculus and Staphylococcus aureus with 15 samples.

How the data were processed

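RNA sequencing of S. aureus biofilm (2 groups of 3 libraries) and of mouse peri-implant tissue (1 group of 3 libraries) was re-analysed from the deposited processed tables. Groups were taken from the sample labels, and columns were matched to samples by title. Of 15 labelled samples, 9 were used. The 6 mouse samples of day 10 were not analysed here, since no column of the tables used carries their titles. The 2 tables also hold 6 per-sample columns, 3 in each, whose names match no labelled sample of the series; they were not used. No labelled group received only 1 component of MnPM+US.

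For S. aureus, the authors deposited raw counts per annotated locus, per the file headers, with product descriptions and pathway terms. The submitters' processing notes name Trimmomatic and DESeq without versions, roles or order. The aligner, the counting tool, its use of strand and the genome build are not given in the sources used here, so genes with near-identical copies are uncertain. Loci are given by the tags in the file, as no S. aureus annotation was used for coordinates. The table has 2727 rows, of which 2669 are annotated loci. The other 58 are predicted transcripts that name no gene. They held 1.40% to 1.56% of the counts in untreated and 0.713% to 0.768% in treated libraries and were kept out of tests and library sizes.

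For mouse tissue, the deposited table gives normalised expression values per gene symbol with 2 decimals, for 18349 genes, of which 2563 are listed at 0 in all 3 libraries and 0 are mitochondrial (mt-) genes. Its header names no unit. Column totals ran from 701350 to 796800, and rounding to 2 decimals hides the step of a single read, so the depth is unknown. The values were only described, as means with SD over 3 libraries, without a test. The libraries correlated at 0.997 or more across genes on a log2(value + 1) scale; genes are not independent replicates. Chromosomal positions of named mouse genes come from the GENCODE M21 annotation of GRCm38, in which 17562 of the listed symbols were found; the build the authors used is not given in the sources used here.

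Differential abundance used edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr (2474 of 2669 loci tested), glmQLFit with robust estimation, and the two-sided glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are MnPM+US over untreated with edgeR's prior count of 0.125, standard errors are derived from the quasi-likelihood F statistic, and CPM are TMM-scaled. A count of 3, taken as the floor, corresponds to 0.416 to 0.453 CPM before scaling. Such floors cover counting error only. Pairs of libraries within a group differed by 23.6 to 50.1 in chi-square per degree of freedom, so none agreed within sampling noise.

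On simulated counts for the same 2474 genes, with 200 genes changed, the fit recovered 84% of 100 genes changed by a log2 of 1 and 47% of 100 genes changed by 0.5, with 13 calls among 2274 unchanged genes. The list test called 5 of 5 changed lists and 0 of 15 unchanged ones. Genes were simulated independently of one another, so this does not cover correlated lists, and estimated correlations in the data reached 0.49. Nor does it cover changes as broad as in the data, where 1869 genes were called.

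The 26 S. aureus gene lists and the mouse lists were fixed, with the tests, before the data were examined. The symbol column of the S. aureus table holds mostly locus tags of other genomes, so members were matched by their deposited product descriptions, after the table was seen and before any test. This gave 466 loci, 439 of them tested; 2 siderophore loci with truncated descriptions were left out before any test. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Camera compares a list with the other genes. Estimated correlations and fry were alternatives; fry asks whether a list's genes move, on balance, one way.

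Genes were named by a rule set beforehand: the 10 raised and 10 lowered genes with the largest fold change that passed the threshold, had non-overlapping groups and at least 10 CPM in the higher group; up to 4 members per list with the smallest adjusted p; and a fixed set of names. The rule asked for a gene symbol; a named product stood in for it, and hypothetical, domain-only, transposase and phage rows were passed over. Some list members outside the rule (the members of the heat shock, SOS and regulator lists that moved against or apart from the rest, the regulator gene of the manganese list, groEL, dnaK, the arginine deiminase gene and the nitrite transporters) were named after their values were seen. For mouse lists, which have no test, members were taken from the 4 with the highest means.

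The alternatives tried were DESeq2 size factors and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond removing genes with 0 counts throughout, a filter of 50 counts in 3 libraries, an added threshold of 1 on the log2 fold change, the replicate number as a block, and leaving out each library. Scaling by library size alone, with and without the 20 most abundant genes, inclusion of the predicted transcripts, and 68 pathway sets from the deposited annotation were added after seeing the data. Figures were drawn with matplotlib 3.10.9.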

Results

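Transcript abundance was measured by RNA sequencing in 2 settings. In the first, Staphylococcus aureus, grown for 48 h as a biofilm on titanium sheets, was incubated for 12 h either untreated or under the label MnPM+US, with nanomaterial at 100 µg/mL. The labels do not spell out MnPM or US; the series title speaks of oxygen-evolving metalloantibiotics and of biofilm infection in orthopaedics. Each S. aureus group held 3 libraries, with 6617905 to 6981824 counts on annotated genes in the untreated libraries and 6959183 to 7214651 in the treated ones. In the second, peri-implant tissue of infected ICR mice, an outbred stock, was digested to single-cell suspensions. Its 3 untreated libraries of day 3 are described by their levels, since the untreated and MnPM+US tissue of day 10 was not analysed here.

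The first comparison asks how the biofilm transcriptome differed after MnPM+US. Most heat shock and nitrate respiration genes rose, and most virulence regulator genes, sigB among them, fell. The chaperone gene clpB (DA471_RS06445), whose product pulls aggregated proteins apart, went from 866 ± 55.2 to 28870 ± 2917 CPM (TMM-scaled, SD, n = 3), a log2 fold change of 5.06 (SE 0.13). The 3 genes of a metal ABC transporter in the manganese transport list had log2 fold changes from -4.34 to -4.01. Of 2474 genes tested, 1869 (75.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 937 higher and 932 lower in the treated biofilm. Of these, 511 higher and 469 lower genes also differed by a log2 of at least 1. The 2 groups did not overlap in CPM for 1916 genes (77.5%), where chance gives 10% for 3 against 3.

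The split between higher and lower depended on the scaling of the libraries. The 10 most abundant genes of each library took 21.7% to 24.2% of its counts in the untreated group and 35.1% to 37.4% in the treated group. With TMM scaling the median log2 fold change over all genes was -0.02 and 50.1% of the called genes were higher. Scaling by library size alone, a setting chosen after seeing the data, moved that median to -0.55 and the split to 549 higher and 1326 lower (29.3% higher). Fold changes are therefore relative to the median gene. Scaling by library size also added lower calls to most lists, and the lists whose balance it turned are given with both counts. For lists where leaving out 1 library moved a count by over 1.5 times or turned the balance, that library is named. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

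**Figure D1:**
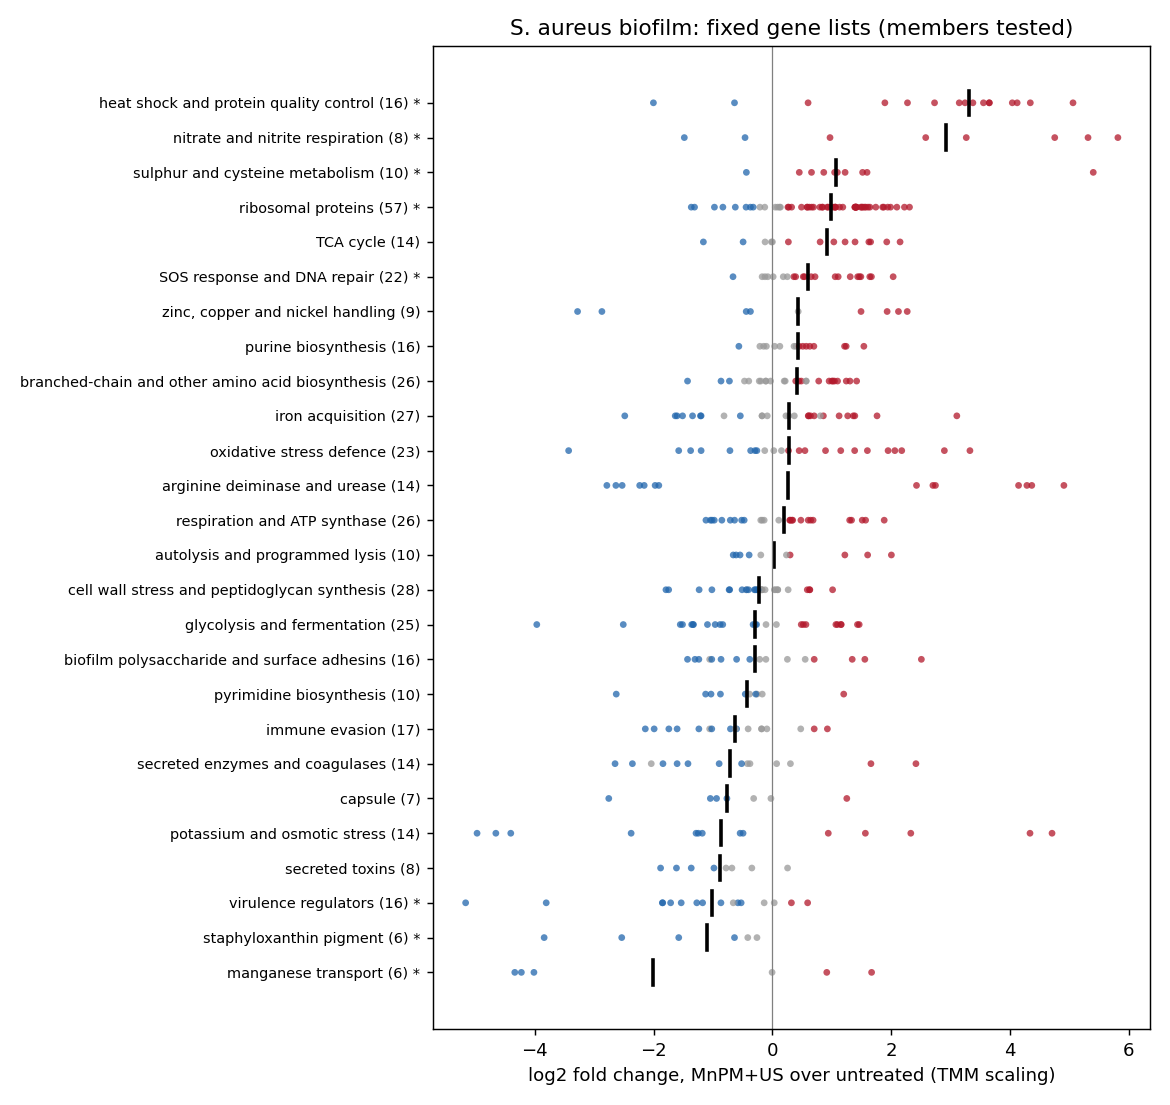
Each row is one of the 26 gene lists, with the number of members tested in brackets, and each point is one member's log2 fold change of MnPM+US over untreated (3 libraries per group, TMM scaling). Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, black bars mark list medians and stars mark the 8 lists called by camera with its preset correlation, of which 0 were called with an estimated correlation; the heat shock list has the highest median, 3.31, and the manganese transport list the lowest, -2.01.

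Heat shock and protein quality control had the highest median of the 26 lists. Of 16 members tested, 14 rose and 2 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 3.31. Besides clpB, the repressor gene ctsR (DA471_RS12260) rose by 4.34 (SE 0.13) and a gene deposited as an arginine kinase (DA471_RS12270) by 4.04 (SE 0.12). A Clp protease ATPase subunit (DA471_RS12275) rose by 4.12 (SE 0.12). The general chaperones dnaK (DA471_RS07670) and groEL (DA471_RS09575) rose by 3.55 and 2.73. The members that fell were hslU (DA471_RS00910), an ATPase subunit of a protease, at -0.64, and another Clp ATPase subunit (DA471_RS05705), which went from 799.8 ± 50.9 to 199.5 ± 10.9 CPM (SD, n = 3). Camera called the list at an adjusted p of 4.4e-15; the adjusted p was 0.27 with an estimated correlation.

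Nitrate and nitrite respiration had 6 of 8 members higher and 2 lower, as when adjusted over the list alone, with a median of 2.92. The nitrate reductase genes lead it: the beta subunit (DA471_RS04885) went from 32.6 ± 7.44 to 1840 ± 299 CPM (SD, n = 3), a log2 fold change of 5.81 (SE 0.19). The alpha subunit (DA471_RS04890) rose by 4.75, the cofactor assembly chaperone (DA471_RS04880) by 5.31 and the putative nitrate transporter narT (DA471_RS04840) by 3.26. Both formate/nitrite transporter genes (DA471_RS04925, DA471_RS08845) fell, with log2 fold changes of -1.48 and -0.46. Camera gave an adjusted p of 3.5e-05, which was an adjusted p of 0.34 with an estimated correlation.

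Metal handling moved both ways. In the manganese transport list, 2 of 6 members rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.34 with an estimated correlation). The substrate-binding (DA471_RS12845), permease (DA471_RS12850) and ATP-binding (DA471_RS12855) genes of the metal ABC transporter fell, with log2 fold changes of -4.23 (SE 0.16), -4.01 (SE 0.19) and -4.34 (SE 0.13), the first from 159 ± 24.4 to 8.42 ± 1.91 CPM (SD, n = 3). Their deposited descriptions name no metal. A metal-dependent regulator gene of the list (DA471_RS12860) stood at 124 ± 21.7 and 124 ± 19.1 CPM (adjusted p = 0.97). Both divalent metal cation transporter genes rose, DA471_RS07790 by 1.67 and DA471_RS11905 by 0.91. Of 9 zinc, copper and nickel genes, 4 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.93); their median was 0.43 and their mean 0.14, while camera's direction was down. Without treated replicate 2, 5 rose and 4 fell, and by library size alone camera's direction was up. The median was -0.10 by library size alone, against -0.55 for all genes. It ranged from 0.225 without treated replicate 3 to 0.59 without treated replicate 2 when 1 library was left out. The copper chaperone copZ (DA471_RS05760) rose by 1.93 and a copper-exporting ATPase (DA471_RS05755) by 1.49, while the zinc efflux gene czrB (DA471_RS06720) fell (-2.87), as did its repressor gene czrA (DA471_RS06725, -3.28). Of 27 iron acquisition genes, 11 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.93); by library size alone 5 rose and 12 fell. Without untreated replicate 2, 9 rose and 11 fell, and camera's direction turned from up to down there and without treated replicate 2 (11 rose, 10 fell). The ferrous iron transport gene feoA (DA471_RS05720) rose by 3.10 and the iron-storage gene ftnA (DA471_RS10350) fell from 13728 ± 436 to 4512 ± 551 CPM (SD, n = 3).

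Oxidative stress defence was mixed. Of 23 members, 12 rose and 8 fell, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.12); by library size alone 9 rose and 12 fell. Without untreated replicate 2, 11 rose and 5 fell, and without treated replicate 2, 12 and 5. The alkyl hydroperoxide reductase gene ahpF (DA471_RS08445) rose by 2.89 (SE 0.12), a peroxiredoxin (DA471_RS08440) by 2.18 and a gene described as mercuric reductase (DA471_RS12645) by 3.32. Catalase (DA471_RS02795) rose by 1.38. Of the 2 superoxide dismutase genes, DA471_RS07535 rose by 0.89 and DA471_RS11025 fell by 1.38. The iron-sulphur cluster repair gene scdA (DA471_RS09085) fell by 3.43. The SOS response and DNA repair list had 15 of 22 members higher and 1 lower, lexA, also adjusted over the list alone, with a median of 0.60. Camera called it at an adjusted p of 0.024, which was an adjusted p of 0.27 with an estimated correlation. By library size alone it had 9 higher and 6 lower and an adjusted p of 0.071, where the other settings with preset correlation gave 0.023 to 0.031. Its median there was 0.07 against -0.55 for all genes, and with TMM scaling 0.60 against -0.02. Members that rose include the excision repair gene uvrC (DA471_RS12130, 2.03), the branch migration helicase gene ruvB (DA471_RS07980, 1.49) and gyrase subunit A (DA471_RS13305, 1.31). The repressor lexA itself (DA471_RS02825) fell by 0.66 and recA (DA471_RS00735), the strand exchange protein, rose by 0.36 with TMM scaling but stood at -0.17 by library size alone.

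Of 16 virulence regulators, 2 rose and 11 fell, as when adjusted over the list alone, with a median of -1.02 (camera adjusted p = 0.011; adjusted p = 0.27 with an estimated correlation). Without untreated replicate 1, treated replicate 2 or treated replicate 3, 1 rose, and 11 or 12 fell; by library size alone none rose and 13 fell. The stress sigma factor gene sigB (DA471_RS02230) fell from 603 ± 59.9 to 167 ± 19.7 CPM (SD, n = 3), a log2 fold change of -1.85 (SE 0.12). Its anti-sigma factor (DA471_RS02225) and the antagonist of that factor (DA471_RS02220) also fell (-1.85 and -1.54). A Sar-family gene deposited as an accessory regulator (DA471_RS13035) had a log2 fold change of -5.16 (SE 0.37), and one deposited as staphylococcal accessory regulator A (DA471_RS11135) of -3.81. Another row described by the crystal structure of SarA (DA471_RS12770) had a value of -0.66 (SE 0.30, adjusted p = 0.10). The agr response regulator is not named in the deposited descriptions. The staphyloxanthin pigment list, which also holds sigma B-linked genes, had 4 of 6 members lower and none higher, also adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.27 with an estimated correlation). Its largest fall was in an Asp23/Gls24 family gene (DA471_RS03455), an alkaline shock protein, from 10284 ± 1861 to 717 ± 26.4 CPM (SD, n = 3). The carotenoid synthesis gene for phytoene desaturase (DA471_RS05775) fell by 1.58.

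Ribosomal protein genes rose in 43 of 57 cases and fell in 8, also adjusted over the list alone, with a median of 0.98 with TMM scaling; by library size alone 33 rose and 16 fell, with a median of 0.45. Those for L17 (DA471_RS03955), L14 (DA471_RS04040) and S15 (DA471_RS00800) rose by 2.31, 2.22 and 2.09. Camera called the list at an adjusted p of 9.4e-05, which was an adjusted p of 0.61 with an estimated correlation. Sulphur and cysteine metabolism had 9 of 10 members higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.34 with an estimated correlation). A cysteine synthase family gene (DA471_RS08145) rose from 19.1 ± 4.88 to 808 ± 108 CPM (SD, n = 3) and the L-cystine transporter gene (DA471_RS08430) rose by 1.52.

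**Figure D2:**
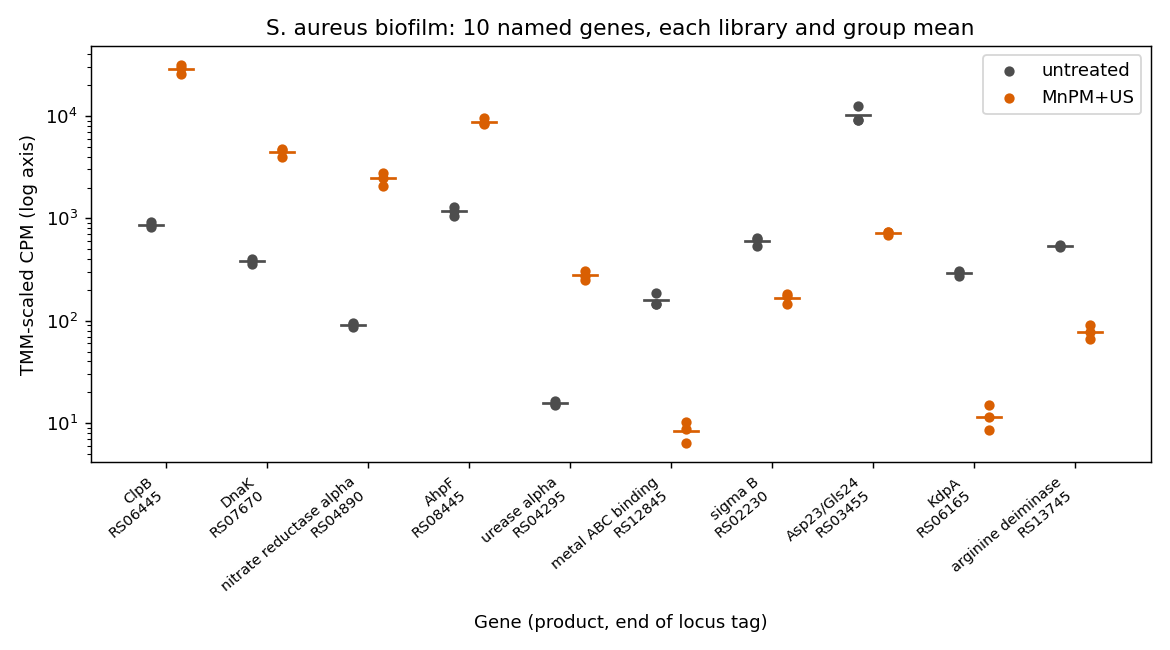
TMM-scaled CPM on a log axis for 10 genes named in the text, chosen after their values were seen, with one point per library (3 untreated in dark grey, 3 MnPM+US in orange) and a line at each group mean. The groups do not overlap for any of the 10; ClpB lies at a mean of 866 CPM untreated and 28870 CPM treated, and the metal ABC transporter binding protein at 159 and 8.42 CPM.

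The 15 lists that follow, like those of oxidative stress, iron, and zinc, copper and nickel, were not called by camera. Arginine deiminase and urease genes all passed, 7 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.31): the 7 urease genes, whose enzyme releases ammonia from urea, rose, the gamma subunit (DA471_RS04285) by 4.91 and the alpha subunit (DA471_RS04295) by 4.14. The 7 arginine deiminase pathway genes fell, arginine deiminase (DA471_RS13745) by 2.79. Potassium and osmotic stress genes also split, with 5 of 14 higher and 9 lower, likewise adjusted over the list alone (camera adjusted p = 0.58). The potassium-transporting ATPase subunits A, B and C (DA471_RS06165, DA471_RS06160, DA471_RS06155) fell, with log2 fold changes of -4.66, -4.40 and -4.97. The choline dehydrogenase (DA471_RS06025) and betaine-aldehyde dehydrogenase (DA471_RS06030) genes, which make the osmoprotectant glycine betaine, rose by 4.34 and 4.71. A second set of potassium ATPase genes and a second set of arginine pathway genes are annotated, so reads could have been divided between copies.

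In central metabolism, 9 of 14 TCA cycle genes rose and 2 fell (camera adjusted p = 0.079), and 7 rose and 5 fell by library size alone. With the preset correlation camera's adjusted p ranged from 0.024, without treated replicate 3, to 0.18, by library size alone. With an estimated correlation camera's adjusted p was 0.61. Citrate synthase (DA471_RS00200) rose by 1.39 and phosphoenolpyruvate carboxykinase (DA471_RS01165) by 2.15. Of 25 glycolysis and fermentation genes, 9 rose and 14 fell (camera adjusted p = 0.24). The diphosphoglycerate-dependent phosphoglycerate mutase (DA471_RS05005) fell from 2251 ± 221 to 144 ± 18.3 CPM (SD, n = 3), while the bisphosphoglycerate-independent enzyme of the same step (DA471_RS14115) rose by 1.43. Respiration and ATP synthase genes had 13 of 26 higher and 9 lower (camera adjusted p = 0.93), and 5 higher and 13 lower by library size alone, where camera's direction turned from up to down. Without treated replicate 1, 9 rose and 9 fell. Cytochrome ubiquinol oxidase subunit I (DA471_RS11800) rose by 1.51 and cytochrome aa3 quinol oxidase subunit IV (DA471_RS11645) fell by 1.12. Each of these 3 lists kept its counts when adjusted over the list alone.

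Of 16 purine genes, 8 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.63), and 1 rose and 5 fell by library size alone. The inosine monophosphate dehydrogenase gene (DA471_RS08390) rose by 0.63 with TMM scaling. Of 10 pyrimidine genes, 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.33), led by the regulator pyrR (DA471_RS06620), which fell by 2.63. Of 26 branched-chain and other amino acid genes, 12 rose and 3 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.71), and 3 rose and 8 fell by library size alone. Without untreated replicate 2, 7 rose and 4 fell, and without untreated replicate 3, 6 and 2. A phosphoglycerate dehydrogenase gene (DA471_RS10525), at the start of serine synthesis, rose by 1.10.

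Of 16 biofilm polysaccharide and adhesin genes, 4 rose and 7 fell (camera adjusted p = 0.72): clumping factor clfA (DA471_RS13945) rose by 1.34 and the antigen gene isaB (DA471_RS13725) fell by 1.30. The gene icaA (DA471_RS13580), for the biofilm polysaccharide synthase, lay at 1.67 ± 0.40 and 2.49 ± 1.07 CPM (SD, n = 3; adjusted p = 0.24), near 0.416 to 0.453 CPM, the level of 3 counts. Of 17 immune evasion genes, 2 rose and 8 fell (camera adjusted p = 0.24), among them staphylokinase (DA471_RS10025, -1.60); by library size alone none rose and 13 fell. Of 14 secreted enzymes and coagulases, 2 rose and 7 fell (camera adjusted p = 0.41), and 1 rose without untreated replicate 1 or treated replicate 1 (9 and 6 fell) and by library size alone (10 fell); the von Willebrand factor binding protein gene (DA471_RS13940) rose by 2.42 and staphopain B (DA471_RS11585) fell by 2.36. None of 8 secreted toxin genes rose and 4 fell (camera adjusted p = 0.43). Delta-haemolysin (DA471_RS09545) fell by 1.88 (SE 0.55, adjusted p = 0.033), a call that ended without any 1 of the treated libraries (adjusted p of 0.11, 0.059 and 0.10 without treated replicates 1, 2 and 3). Alpha-hemolysin (DA471_RS12220) had a value of -0.78 (adjusted p = 0.077; 0.0041 by library size alone) at 2.86 ± 0.293 CPM untreated (SD, n = 3). Of 7 capsule genes, 1 rose and 4 fell (camera adjusted p = 0.59), among them capA (DA471_RS10940, -2.75); 2 fell without untreated replicate 1, treated replicate 1 or treated replicate 3. All 5 of these lists kept their counts when adjusted over the list alone.

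Of 28 cell wall genes, 4 rose and 13 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.33), and 1 rose and 23 fell by library size alone; the methicillin resistance gene mecA (DA471_RS13125) rose by 1.01 and the teichoic acid esterase gene fmtA (DA471_RS11640) fell by 1.75. Of 10 autolysis genes, 4 rose and 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.93), with the lytic transglycosylase gene sceD (DA471_RS02050) up by 2.00. By library size alone 3 rose and 5 fell; 3 rose and 4 fell without untreated replicate 1 or 3 or treated replicate 1 or 3, and 4 rose and 3 fell without treated replicate 2. Among the genes with the largest changes outside these lists, the multidrug efflux gene mepA (DA471_RS08680) rose from 6.36 ± 1.20 to 450 ± 70.1 CPM (SD, n = 3), a log2 fold change of 6.14 (SE 0.16). An L-threonylcarbamoyladenylate synthase gene (DA471_RS06430), for a transfer RNA modification, rose by 5.96 (SE 0.40) from 0.969 ± 0.834 CPM, near the level of 3 counts, which leaves the size uncertain, and an aminotransferase gene (DA471_RS08140) by 4.53. A helix-turn-helix regulator gene (DA471_RS13375) fell (-4.75), as did that for the activating protein of anaerobic ribonucleotide reductase (DA471_RS06060, -4.25), an oxygen-sensitive route to DNA precursors.

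The comparisons of MnPM+US with untreated mouse tissue on day 10, and of untreated tissue between days 10 and 3, were not analysed here. In untreated day 3 tissue, neutrophil transcripts had the highest values. S100a9 (chromosome 3, 90692632 to 90695721, GRCm38) had the highest value of 18349 listed genes, 76102 ± 9464 (SD, n = 3, in the deposited expression unit, which the table does not name), followed by S100a8 (chromosome 3, 90668978 to 90670035) at 54755 ± 13917 and the granule gene Ngp (chromosome 9, 110419747 to 110423012) at 27184 ± 524. All 16 neutrophil markers had a mean of at least 1 and together held 26.6% of the summed values. The 8 neutrophil granule precursor genes held 0.628%, most of it from Chil3 at 3050 ± 274, which is also in the alternative macrophage list. Mpo stood at 450 ± 22.2 and Elane at 422 ± 12.3 (SD, n = 3).

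Monocyte and macrophage markers held 1.38% of the summed values, most of it from Lyz2 at 9250 ± 765, a gene that neutrophils also express, with Csf1r at 114 ± 3.30 (SD, n = 3). Inflammatory cytokine and chemokine genes held 0.671%: Il1b (chromosome 2, 129364570 to 129371139) stood at 2178 ± 46.8 and ranked 30 among all genes, Ccl3 at 986 ± 17.7 and Tnf at 408 ± 9.98. All 15 dissociation and immediate-early stress genes had a mean of at least 1, with Zfp36 at 885 ± 37.4 and Junb at 647 ± 52.8. The tissue was digested to single cells, and whether preparation shaped these or other levels was not tested. Of the T cell markers, 3 of 15 listed had a mean of at least 1, Cd3e was listed at 0.05, 0.05 and 0 in the 3 libraries and Cd8a stood at 0.12 ± 0.07, while Cd3d stood at 44.2 ± 5.04 (SD, n = 3). B and plasma cell markers had 10 of 12 at a mean of at least 1, led by Cd79a at 56.2 ± 12.2. Mast cell and basophil markers were led by Hdc at 386 ± 14.3, with Mcpt8 at 153 ± 18.9, Cpa3 at 9.25 ± 0.53 and Kit at 7.72 ± 0.59. Of 9 listed, 6 had a mean of at least 1 and 2 were at 0 in all 3 libraries. Dendritic cell and MHC class II genes were led by Cd74 at 167 ± 20.9.

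Of 22 fibroblast and matrix genes, 7 had a mean of at least 1, with Col1a1 (chromosome 11, 94936224 to 94953042) at 1.59 ± 0.67 and Fn1 at 241 ± 13.3 (SD, n = 3). Of 14 endothelial markers 4 did, and of 18 skeletal muscle genes 3 did; Acta1 was listed at 0.05, 0.05 and 0 in the 3 libraries. No cartilage, keratinocyte or muscle regeneration gene did. Erythroid genes held 0.713%, most of it from Hba-a1 at 4175 ± 191, although red cells were lysed during preparation. Of the nucleic acid sensing genes, Cgas stood at 4.03 ± 0.23 and Sting1 at 10.5 ± 0.45, and 15 of 16 listed had a mean of at least 1. Ifnb1 was listed at 0, 0.71 and 0 in the 3 libraries, and Vegfa stood at 21.7 ± 2.97 (SD, n = 3). Of 29 interferon-stimulated genes listed, 25 had a mean of at least 1, as did all 17 cell cycle genes. Metal handling and oxidative stress genes held 2.62% of the summed values, most of it from Fth1 at 16173 ± 381 (SD, n = 3), a ferritin gene. The depth behind these values is unknown, and no comparison was made with another table.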

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

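Scaling by library size, with or without the most abundant genes, was chosen only after the results were seen. The count of genes called stayed within 1.5 times the reported one under the other scalings, tests and filters planned, with no gene called in the opposite direction. Requiring a log2 fold change of at least 1 left 511 higher and 469 lower genes, by its own construction. Library size alone moved the split more than the total, with 549 higher genes, all of them among the 937 reported, and 1326 lower genes, 12 of them reported as higher. Of the 116 genes named by rule, it reversed recA (-0.17) and the GMP synthase gene DA471_RS08385 (-0.0797), neither called there, where the median gene lay at -0.55. With library totals taken without the 20 most abundant genes, 794 were higher and 1046 lower, and recA was no longer called (adjusted p = 0.11, over a range that reaches 0.17 by library size alone).

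Leaving out 1 library at a time gave 860 to 912 higher genes, 851 to 894 of them shared with those reported, and 862 to 903 lower genes, 839 to 881 of them shared. The same settings called 8 to 9 lists; the TCA cycle list was added without treated replicate 3 (adjusted p = 0.024). With an estimated correlation camera called 0 of 26 lists, 4 of them at an unadjusted p under 0.05, while fry called 22. The cause was not tested, though fry asks another question than camera. For the SOS, staphyloxanthin and virulence regulator lists the estimates (-0.0091, -0.052 and 0.0057) lay below the preset 0.01. Their unadjusted camera p still rose, from 0.0073, 0.0040 and 0.0017 to 0.042, 0.042 and 0.032. This argues against a higher correlation as the reason in these lists. The other called lists had estimates of 0.088 to 0.49. Since p also rose without a higher correlation, p-values with an estimated correlation cannot be read as an effect of correlation alone.

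The replicate numbers were not taken to pair the libraries: deviations from the group means correlated at 0.245, -0.0447 and 0.184 for numbers 1, 2 and 3, and not every library correlated best with its own number. With the number as a replicate block, 939 genes were higher, 930 lower and 8 lists were called. A fit with all groups of the table was not run, since its other columns were not used. The alternatives for the day 10 mouse comparisons were not run either. How depth limits recovery was not tested; the self-test, over all abundances, recovered 47% of genes changed by a log2 of 0.5.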

Other observations

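The tests of pathway sets, of predicted transcripts, of other splits, of the heat shock list and of the scaling of sigB were chosen only after the results were seen, as were the abundant loci named. Among the 20 most abundant transcripts, which together took 29.5% to 31.9% of the counts in untreated and 45.4% to 46.8% in treated libraries, shares moved both ways. The Dps-type DNA starvation protein (DA471_RS06755), which binds iron and DNA, went from 0.944% to 2.73% of the counts of a library on average (3 libraries per group, shares without TMM scaling). The Clp protease subunit (DA471_RS14155) went from 0.331% to 2.86%, and clpB (DA471_RS06445) from 0.104% to 2.40%. In the other direction, the ferritin gene ftnA (DA471_RS10350) went from 1.65% to 0.376%. Smaller falls in share were those of the regulator gene spx (DA471_RS11300, 2.45% to 2.06%) and a universal stress protein gene (DA471_RS00275, 1.64% to 1.47%). Both fell by less than the median gene, which lay at a log2 of -0.55 by library size alone, so relative to it they did not fall. The spx shares also overlapped between groups (2.22% in untreated replicate 1, 2.25% in treated replicate 1). The locus with the highest share in the treated libraries (DA471_RS14080), with no description, went from 3.30% to 8.32%, and 2 of the next were hypothetical proteins (DA471_RS06950, 4.04% to 6.45%, and DA471_RS06675, 1.65% to 5.04%).

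Of 68 pathway sets from the deposited annotation with at least 8 tested members, camera with its preset correlation called 1, the ribosome set, with 43 of 58 members higher and 8 lower (adjusted p = 0.00092; adjusted p = 0.90 with an estimated correlation). With estimated correlations 0 of the 68 sets passed, and 0 had an unadjusted p under 0.05. Of the 58 predicted transcripts that name no gene, 25 were higher and 18 lower in edgeR when tested with the annotated loci.

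The real split of the 6 S. aureus libraries called 1869 genes, and the highest of the other splits called 0. Of the 10 splits, 1, the real one, gave as many, and with 10 splits no share under 0.05 can be reached. Each other split mixes treated and untreated libraries, so their difference enters the spread within groups and few calls could follow. The count of 0 therefore tells little about the real split. Near-equal numbers of genes were called higher and lower with TMM scaling, and fewer higher by library size alone. A candidate explanation is that a few abundant transcripts took a larger share of the treated libraries. With the 20 most abundant genes left out of the totals, the median log2 fold change of all genes moved from -0.55 to -0.20, short of the 0.1 around 0 set beforehand and above the -0.3 that would have argued against it. Whether the remaining shift comes from further abundant genes or from a true excess of lower genes cannot be told apart, since counts alone do not give total RNA per cell.

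The rise of the heat shock list was set against the same scaling difference. By library size alone its median log2 fold change was 2.77, against 3.31 with TMM scaling. The shift of the median gene to -0.55 was already known, so this outcome could be foreseen and is no independent test. It shows only that the choice between these scalings does not account for the rise. Treatment with MnPM+US is the difference the design names. Whether the nanomaterial, the US component or a secondary change such as growth state lies behind the rise stays open, since no group with 1 component was used. The rise is therefore not assigned to any of them, and technical sources beyond this choice of scaling were not examined for it.

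A last pattern is the joint fall of sigB, its regulator genes and the Asp23/Gls24 gene. Over 3 other scalings the log2 fold change of sigB was at most -1.85, but each of them lowered the median gene, so none could have raised sigB. Against the median gene these genes stayed low. By library size alone sigB, its anti-sigma factor, the antagonist and Asp23/Gls24 lay at -2.38, -2.37, -2.06 and -4.375, with the median gene at -0.55. With TMM scaling sigB lay at -1.85 and the median gene at -0.02. Scaling moves all log2 fold changes by nearly the same amount, so the distance to the median gene was bound to stay. It is therefore no test of scaling, and the fall of these genes is given only relative to the median gene. Whether their amount per cell fell stays open. The hypothesis that sigma B activity was lower in the treated cells was tested on 5 other products held to depend on sigma B, listed before their values were looked at. Their median log2 fold change was -1.47, and 4 of 5 were called lower: both CsbD family genes (DA471_RS02305, -2.43; DA471_RS07895, -2.55), galU (DA471_RS05445, -1.47) and hchA (DA471_RS12420, -1.17). Over all genes tested 932 of 2474 were called lower, and the CsbD genes share a family, so a count among 5 products carries limited weight. The RidA family gene (DA471_RS03635) had a value of -0.16 (adjusted p = 0.16). This is consistent with lower sigma B activity, as a hypothesis; sharing of reads between family members and a change of growth state, which the tables do not test, remain open too.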
